A study of Homo sapiens with 12 samples.

How the data were processed

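The deposited tables hold intensity values that the authors quantile-normalized on the linear scale without background subtraction, together with summarized intensities before normalization and a detection p-value per probe and array, per the file headers. The processing notes name GenomeStudio 2010.2 and the design text BeadStudio; the settings of either are not given in the sources used here. Per the labels' protocols, RNA was isolated with TRI reagent, checked on a Bioanalyzer and turned into biotin-labelled cRNA with an Ambion MessageAmp kit. The detection p-value of each probe, as deposited by the authors, was used to judge whether it lay above background.

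The intensities before normalization were corrected, quantile-normalized and log2-transformed with neqc of limma 3.58.1 (R 4.3.3), with an offset of 16. The table used here holds no control probes, so the background was estimated from the detection p-values. Of 48782 probes, the 17792 with a detection p-value under 0.05 on both arrays of at least 1 of the 6 groups were tested. Probes were named through their gene identifiers: 28083 had 1 symbol, 13 several and 20686 none, and 14277 of the probes tested carried 1 symbol, for 10721 genes. No coordinates were used. Fold changes against a group in which no array detected the probe are lower bounds ("at least"), with each array of that group set to the higher of its own signal and its lowest detected signal. These bounds hold for the background correction used.

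A linear model with 1 mean per group was fitted with limma to all 12 arrays (6 residual degrees of freedom, 4.74 prior), and moderated tests were 2-sided and adjusted by the Benjamini-Hochberg method within each comparison at a false discovery rate of 0.05. Comparisons were treated against untreated in each line, their mean over the 3 lines, the differences between lines (pairwise and by an F test) and the untreated lines against each other. Intervals are at 95%. SD is between the 2 arrays of a group and SE is from the model. Per line, 23 gene lists (431 genes, of which 404 had a named probe and 350 were tested) were tested with camera at a preset correlation of 0.01, with 1 probe per gene, that with the highest mean signal, and again with an estimated correlation. The lists are the FCRL and Fc gamma receptor family, B cell receptor signalling, NF-kB targets, immediate early and ERK feedback genes, type I interferon response, cell cycle and DNA replication, BCL2 family and death receptors, p53 targets, unfolded protein response, ATF4 amino acid response, cholesterol biosynthesis, hypoxia and glycolysis, MHC class II presentation, germinal centre B cell, plasma cell, B cell identity, B cell activation markers and cytokines, heat shock, MYC targets and ribosome biogenesis, markers of T and NK cells, of myeloid cells and of epithelial, fibroblast and erythroid cells, and control genes.

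The groups, comparisons, filter, lists, alternatives and the rule for naming genes were chosen before the data were examined; the list test on differences between lines was added after. The rule names, per line, the 10 called probes with the largest change each way or, with none called, the 3 with the smallest p each way as values only. It also names the FCRL genes in every line, up to 4 members per list and line with the smallest p, genes called in more than 1 line or by the F test, and, between untreated lines, members of the germinal centre, plasma cell, B cell identity and FCRL lists. Only probes with 1 symbol are named, and from those the rule allows the text gives a selection.

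To see what 2 arrays per group can detect, all 12 arrays were simulated. Line means and moderated probe spreads came from the fit, and noise was drawn independently for each probe. In 1 line at a time, changes of 4 sizes were added to 50 probes each, all at once. Many changed probes make the adjusted threshold easier to reach, so recovery may be lower where only a few probes change. Moderated spreads differ less between probes than the measured ones. The full change was added to the normalized signal also for probes near background, where a real change would appear smaller. For these reasons too, the counts may overstate recovery. At 2-fold, 38 were recovered in HS-Sultan, 46 in RPMI8226 and 40 in SU-DHL-5, and at 3-fold 50, 50 and 49. At 1.5-fold 13, 12 and 15 were recovered. Beside them 7, 9 and 9 unchanged probes were called, and 0 in the unchanged lines. A list of 20 probes moved by 0.3 in HS-Sultan passed with camera, as did 6 of 200 unmoved lists (3%) at an unadjusted level of 0.05. These lists were random probes with independent noise, so the share does not show how camera behaves for genes that vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.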

Results

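Gene expression was measured on 12 Illumina HumanHT-12 v3 BeadChips, arrays of bead-bound oligonucleotide probes that give 1 fluorescence intensity per probe. The RNA came from 3 established human cell lines of the B lineage. Per the labels, HS-Sultan is a Burkitt's lymphoma line, RPMI8226 a myeloma line and SU-DHL-5 a line from diffuse large B cell lymphoma. The labels describe all 3 as carrying FCRL2, an Fc receptor-like membrane protein of B cells whose cytoplasmic tail holds immunoreceptor tyrosine-based motifs. After 16 h of preculture the cells were left untreated or kept for 24 h with a mix of the monoclonal antibodies B24 and B62, both directed against FCRL2, at 10 µg/ml each. Each line contributed 2 untreated and 2 treated arrays, which the design text calls biological duplicates. The controls were untreated cells, and the labels name no isotype control antibody. Between 15199 and 17098 of the 48782 probes (31.2 to 35.0%) were above background per array, and the median intensity per array was 116 to 128. Across the 17792 probes tested, log2 signals of replicate arrays correlated with r of 0.992 to 0.994. Treated and untreated arrays of 1 line correlated equally closely, at 0.992 to 0.994. Arrays labelled HS-Sultan and RPMI8226 correlated at 0.984 to 0.986. Arrays labelled SU-DHL-5 correlated with those labelled HS-Sultan at 0.878 to 0.880 and with those labelled RPMI8226 at 0.871 to 0.873. These correlations are across probes, which are not independent replicates. With 1 line per disease, a difference between lines is not separable from a difference between diseases.

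FCRL2, the target of the antibodies, was detected on 12 of 12 arrays. In untreated cells its brighter probe (ILMN_1791329) read 11.44 ± 0.020 (SD of log2 signal, n = 2) in HS-Sultan, 11.03 ± 0.032 in RPMI8226 and 10.92 ± 0.082 in SU-DHL-5. With the antibodies the same probe read 11.41 ± 0.018, 11.08 ± 0.16 and 11.09 ± 0.11. None of these differences passed the test: the 95% confidence intervals ran from −0.31 to 0.24 in HS-Sultan, −0.23 to 0.33 in RPMI8226 and −0.11 to 0.45 in SU-DHL-5 on the log2 scale. The dimmer FCRL2 probe (ILMN_1665152) read 7.13 ± 0.0029 in untreated and 7.57 ± 0.039 in treated SU-DHL-5 cells, a difference of 0.44 ± 0.13 (SE) with both treated arrays higher that did not pass (limma, adjusted p = 0.457). Of the other family members, FCRL1 and FCRL6 were detected on 0 of 12 arrays. FCRLA, an intracellular relative of the FCRL receptors that binds immunoglobulin, stood at 13.93 ± 0.11, 14.03 ± 0.042 and 13.59 ± 0.088 in untreated HS-Sultan, RPMI8226 and SU-DHL-5 cells, and at 13.71 ± 0.035, 14.06 ± 0.062 and 13.66 ± 0.10 with the antibodies. The brighter FCRL5 probe stood at 8.91, 7.31 and 10.82 without and 8.95, 7.15 and 10.82 with them. Its dimmer probe (ILMN_2105223) read 7.05 ± 0.091, 5.81 ± 0.34 and 8.83 ± 0.052 without the antibodies. With them it read 6.72 ± 0.14, 5.51 ± 0.038 and 8.90 ± 0.11. In SU-DHL-5, the brighter FCRL3 probe read 9.93 in both conditions and FCRL4 8.41 untreated against 8.48 treated. The dimmer FCRL3 probe (ILMN_1699599) read 8.81 ± 0.098 untreated and 8.45 ± 0.28 treated there. No FCRL gene passed the test in any line.

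The treatment comparison asks whether antibodies bound to FCRL2 alter transcript levels. In HS-Sultan cells no probe passed the test for a difference between antibody-treated and untreated cultures. The genes with the smallest p were close to background in 1 of the conditions and are given as values only. NUMA1, a protein of the mitotic spindle poles, read 6.52 ± 0.16 (SD, n = 2) treated and was not above background untreated (5.35 ± 0.14), which is at least 1.83-fold (adjusted p = 0.472, both treated arrays higher). The zinc finger gene ZNF124 (at least 1.66-fold, adjusted p = 0.509) and CCDC146 (at least 1.29-fold, adjusted p = 0.517) lay higher on both treated arrays. The olfactory receptor gene OR2A1 (at least 1.48-fold), PRAMEF7 (at least 1.24-fold) and the inositol phosphate kinase gene IP6K1 (at least 1.13-fold) lay lower on both treated arrays, each at adjusted p = 0.517. OR2A1 and PRAMEF7 belong to families with near-identical copies, so their probes may not separate the members. Among the fixed lists, CASP8, the initiator caspase of death receptors, differed by 0.93 ± 0.28 (adjusted p = 0.62), SREBF2, a transcription factor of sterol synthesis, by −1.01 ± 0.32 (adjusted p = 0.646), and GRB2, an adaptor of receptor signalling, by 0.29 ± 0.11 (adjusted p = 0.776), with both treated arrays on the same side of both untreated arrays. CD14, a monocyte marker, read 6.03 ± 0.012 untreated and was not above background treated (at least 1.33-fold, adjusted p = 0.601). It was the 1 gene that passed when adjusted over the list alone (adjusted p = 0.041), against 0 over all probes. With limma, 0 of 17792 probes passed at a false discovery rate of 0.05 (lowest adjusted p = 0.194), while 1048 (5.89%) had an unadjusted p under 0.05, against 890 by chance. Confidence intervals lay within 2-fold for 95.7% of probes. Without untreated replicate 1, 2 probes passed, for CACNG8 (−1.54) and GCNT2 (1.37), both at adjusted p = 0.045; with all arrays they differed by −0.94 and 0.90 (adjusted p = 0.62 and 0.592), and they are named after their values were seen. Both were above background on 1 of 2 untreated arrays, and CACNG8 on 0 of 2 treated arrays, so these differences rest partly on background signal.

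On the arrays labelled RPMI8226 no probe passed either. TSNAX, the partner of the nucleic acid-binding protein translin, read 6.10 ± 0.023 treated and was not above background untreated (at least 1.43-fold). MUTYH, a DNA glycosylase of base excision repair, read 7.17 ± 0.026 treated and 6.33 ± 0.16 untreated (1.80-fold), and TXNL1, a thioredoxin-like protein, 8.56 ± 0.018 and 7.78 ± 0.17 (1.72-fold). On the lower side stood TCOF1, a factor of ribosomal RNA synthesis (5.90 ± 0.20 against 6.96 ± 0.18, 2.10-fold), the integrator subunit gene INTS6L (1.67-fold) and the pseudogene HERC2P2 (at least 1.42-fold). Both treated arrays lay beyond both untreated arrays for each of these 6 genes, and each had an adjusted p of 0.539. Among list members, CASP8 differed by −1.01 ± 0.28 (adjusted p = 0.616, both treated arrays lower), the plasma cell surface proteoglycan SDC1 by 0.65 ± 0.25 (adjusted p = 0.759, both higher) and SEC11C, a subunit of the signal peptidase complex, by 0.42 ± 0.12 (adjusted p = 0.62, both higher). SDC1 was above background on 3 of the 4 arrays, with a mean of 5.84, so its difference rests partly on background signal. PRF1, the pore-forming protein of cytotoxic cells, was not above background untreated and read 6.08 ± 0.16 treated (at least 1.41-fold). Adjusted over the list alone, 2 genes passed, PRF1 (adjusted p = 0.00069) and the keratin gene KRT8 (adjusted p = 0.0041), the latter not above background in either condition, against 0 over all probes. Their lists held very few tested members, so this adjustment was slight, and none was made over the lists or lines. With limma, 0 of 17792 probes passed (lowest adjusted p = 0.539) and 1117 (6.28%) had an unadjusted p under 0.05. Confidence intervals lay within 2-fold for 95.6% of probes.

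In SU-DHL-5 cells no probe passed. The genes with the smallest p were measured in both conditions more often than in the other lines. PIBF1, a centrosomal protein, read 7.01 ± 0.038 treated and 6.09 ± 0.28 untreated (1.89-fold; 0.92 ± 0.15, SE), TWF1, the actin-binding protein twinfilin, 7.62 ± 0.058 and 6.88 ± 0.016 (1.67-fold), and THAP10 7.43 ± 0.087 and 6.61 ± 0.079 (1.76-fold). SIGLEC10, an inhibitory sialic acid-binding lectin of B cells, read 6.80 ± 0.057 treated and 7.64 ± 0.16 untreated (1.79-fold lower; −0.84 ± 0.14). MTCH2, a protein of the outer mitochondrial membrane, was detected on 1 of 2 treated arrays and stood 2.03-fold lower, and KRT8 was not above background in treated cells (at least 1.12-fold lower). Each of these 6 genes had an adjusted p of 0.231, with both treated arrays beyond both untreated arrays. Among list members, SPRY1, a feedback inhibitor of receptor tyrosine kinase signalling, read 7.35 ± 0.21 against 6.60 ± 0.15 (0.75 ± 0.14; adjusted p = 0.329, both treated arrays higher). STAP1, a signalling adaptor of germinal centre B cells, differed by 0.67 ± 0.19, BANK1, a B cell scaffold protein, by −0.50 ± 0.15, and the immediate early gene IER2 by −0.80 ± 0.27. Adjusted over the list alone, 3 genes passed, SPRY1 (adjusted p = 0.005), the stress-responsive kinase gene PLK3 (adjusted p = 0.019, at least 1.17-fold higher) and KRT8 (adjusted p = 0.00018), against 0 over all probes. The list of KRT8 held very few tested members, and no adjustment was made over the lists or lines. With limma, 0 of 17792 probes passed (lowest adjusted p = 0.231) and 1419 (7.98%) had an unadjusted p under 0.05. Confidence intervals lay within 2-fold for 95.3% of probes.

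**Figure D1:**
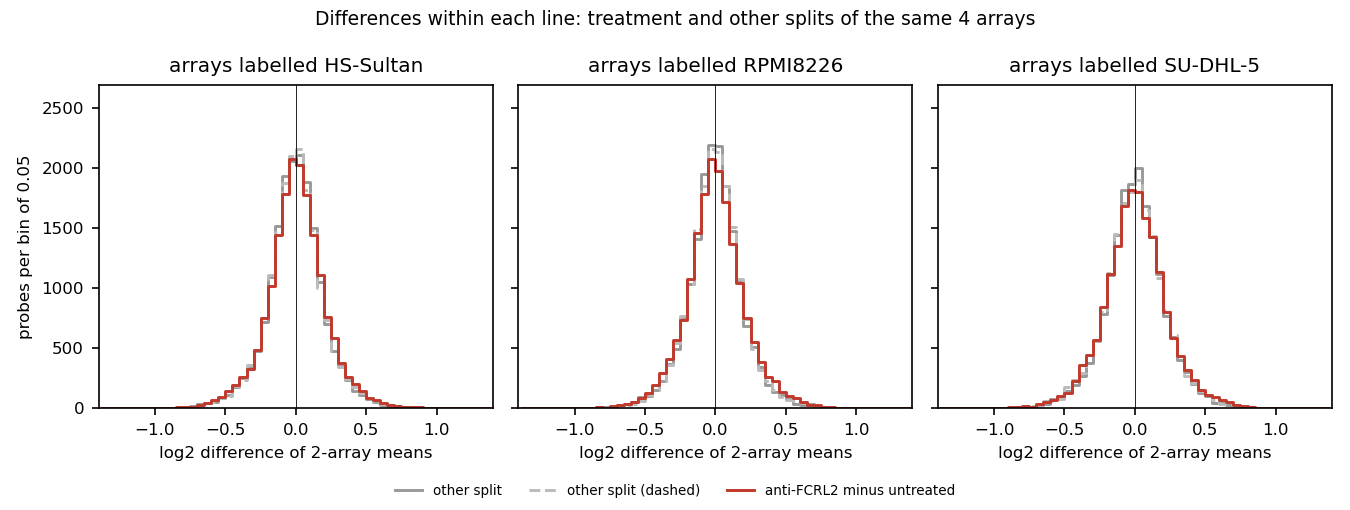
Differences of 2-array means (log2 signal, x axis) counted in bins of 0.05 (probes per bin, y axis) over 17792 probes, for treated minus untreated arrays (red) and for the other 2 splits of the same 4 arrays (grey, solid and dashed) in each line. The distributions nearly coincide, with SDs of 0.214, 0.216 and 0.229 for the treatment in HS-Sultan, RPMI8226 and SU-DHL-5 against 0.198 to 0.222 for the other splits.

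The lines did not share a response that the test could call. The mean treatment effect over the 3 lines passed for 0 of 17792 probes with limma (lowest adjusted p = 0.507), and 1216 (6.83%) had an unadjusted p under 0.05. Here 96.0% of the confidence intervals lay within 1.5-fold, so a common change above that size was excluded for most probes tested. No difference of treatment effects between lines passed: the F test of the line differences passed for 0 probes (lowest adjusted p = 0.635, 1233 at an unadjusted p under 0.05), and the pairwise differences passed for 0, with 1068, 1226 and 1151 probes at an unadjusted p under 0.05. Only 26.3 to 27.6% of the intervals of the pairwise differences lay within 1.5-fold, so differences of that size were not excluded for most probes. Adjusted over the list alone, 4 genes passed between HS-Sultan and RPMI8226, CASP8 (1.94 ± 0.40, SE; adjusted p = 0.0098), SEC11C (−0.73 ± 0.17, adjusted p = 0.02), PRF1 and KRT8. Between HS-Sultan and SU-DHL-5 3 passed, SPRY1, SERPINA9 and KRT8, and between RPMI8226 and SU-DHL-5 1, SPRY1. No size is given for PRF1, KRT8, SPRY1 and SERPINA9, which were not above background in 1 or more of the groups compared, and CASP8 was above background on 1 of 2 untreated arrays of HS-Sultan. Over all probes 0 of these passed, with adjusted p of 0.531 to 0.727. Treatment effects of HS-Sultan and RPMI8226 correlated across probes with r = −0.023, those of HS-Sultan and SU-DHL-5 with r = 0.0043 and those of RPMI8226 and SU-DHL-5 with r = 0.033; 0 calls were shared. For the mean over lines, 4 genes passed when adjusted over the list alone: PLK3, PRF1, CD14 and KRT8. Over all probes each of the 4 had an adjusted p of 0.612. Each of the 4 was above background on no array of at least 1 of the 6 groups, so no size is given. In the split of a line's 4 arrays into pairs, the treatment gave 1048 probes at an unadjusted p under 0.05 in HS-Sultan against 831 at most in the other splits, 1117 against 752 in RPMI8226 and 1419 against 1244 in SU-DHL-5, but 3 splits per line are too few for a share under 0.05.

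Of the 23 gene lists, 1 passed in 1 line: hypoxia and glycolysis in SU-DHL-5, with the preset correlation and by a small amount. Of 18 members tested, 12 lay higher and 6 lower, with a median log2 change of 0.15 and a mean of 0.16 (camera, adjusted p = 0.037; adjusted p = 0.411 with an estimated correlation). The members with the smallest p were KDM3A, a histone demethylase (0.61 ± 0.24, SE), ANKRD37, a hypoxia-induced ankyrin repeat protein (0.44 ± 0.14), P4HA1, a collagen prolyl hydroxylase subunit (0.37 ± 0.19), and PFKFB4, a regulator of glycolytic flux (0.29 ± 0.12). No member passed over all probes or adjusted over the list alone (lowest adjusted p = 0.162), and 3 had an unadjusted p under 0.05. The per-array medians of the list, relative to the mean of the line, were −0.036 and −0.041 untreated and 0.098 and 0.043 treated, so both treated arrays were higher. The same list had a median of 0.015 in HS-Sultan (adjusted p = 0.82), 0.035 on the arrays labelled RPMI8226 (adjusted p = 0.964) and 0.076 over the lines (adjusted p = 0.116). Its difference between lines did not pass, at −0.085 for HS-Sultan minus SU-DHL-5 (adjusted p = 0.564) and −0.11 for RPMI8226 minus SU-DHL-5 (adjusted p = 0.329). The call ended without untreated replicate 1 or 2 or treated replicate 1 or 2 of SU-DHL-5 (adjusted p = 0.125, 0.219, 0.293 and 0.067). It also ended without either treated array of HS-Sultan (0.054) or of RPMI8226 (0.052) and with median scaling (0.062), within a range of 0.011 to 0.411 over 24 alternatives.

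The other 22 lists did not pass in any line, in the mean over lines or in a difference between lines, and their median log2 changes in HS-Sultan, RPMI8226 and SU-DHL-5 follow in that order. Lists close to the receptor were the FCRL and Fc gamma receptor family (−0.21, 0.073 and 0.069), B cell receptor signalling (0.11, −0.022 and −0.077), NF-kB targets (0.014, −0.014 and −0.064) and immediate early and ERK feedback genes (0.015, 0.063 and −0.0086). In HS-Sultan 18 of 24 members of B cell receptor signalling and 10 of 13 germinal centre genes lay higher, both at adjusted p = 0.194. Growth and death lists were cell cycle and DNA replication (0.022, −0.034 and −0.031), MYC targets and ribosome biogenesis (0.0098, −0.059 and −0.033), the BCL2 family and death receptors (0.039, 0.0018 and −0.024) and p53 targets (0.087, 0.021 and 0.17). Stress and metabolic lists were the unfolded protein response (−0.016, −0.00022 and 0.058), the ATF4 amino acid response (0.024, 0.015 and −0.036), heat shock (0.026, 0.053 and 0.068) and cholesterol biosynthesis (0.015, −0.042 and −0.050). Immune lists were the type I interferon response (−0.045, −0.049 and 0.030), MHC class II presentation (−0.067, −0.047 and −0.0038) and B cell activation markers and cytokines (−0.029, −0.0073 and −0.021). Lists of B cell stages were germinal centre B cell (0.10, 0.066 and 0.021), plasma cell (−0.041, −0.011 and 0.021) and B cell identity (−0.0031, 0.028 and −0.083). Markers of other cell types were T and NK cells (−0.30, 0.19 and 0.10; 3 members tested), myeloid cells (−0.096, −0.025 and −0.067; 8 members) and epithelial, fibroblast and erythroid cells (0.0059, −0.25 and −0.18; 2 members), and control genes stood at −0.072, 0.047 and 0.0073. Over the 3 lines the germinal centre list had a median of 0.083 with 10 of 13 members higher (adjusted p = 0.116). Median, mean and test direction differed in sign for 6 lists in HS-Sultan, 6 in RPMI8226, 3 in SU-DHL-5 and 3 in the mean over lines, and for 6, 8 and 8 in the differences between lines, none of which passed.

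**Figure D2:**
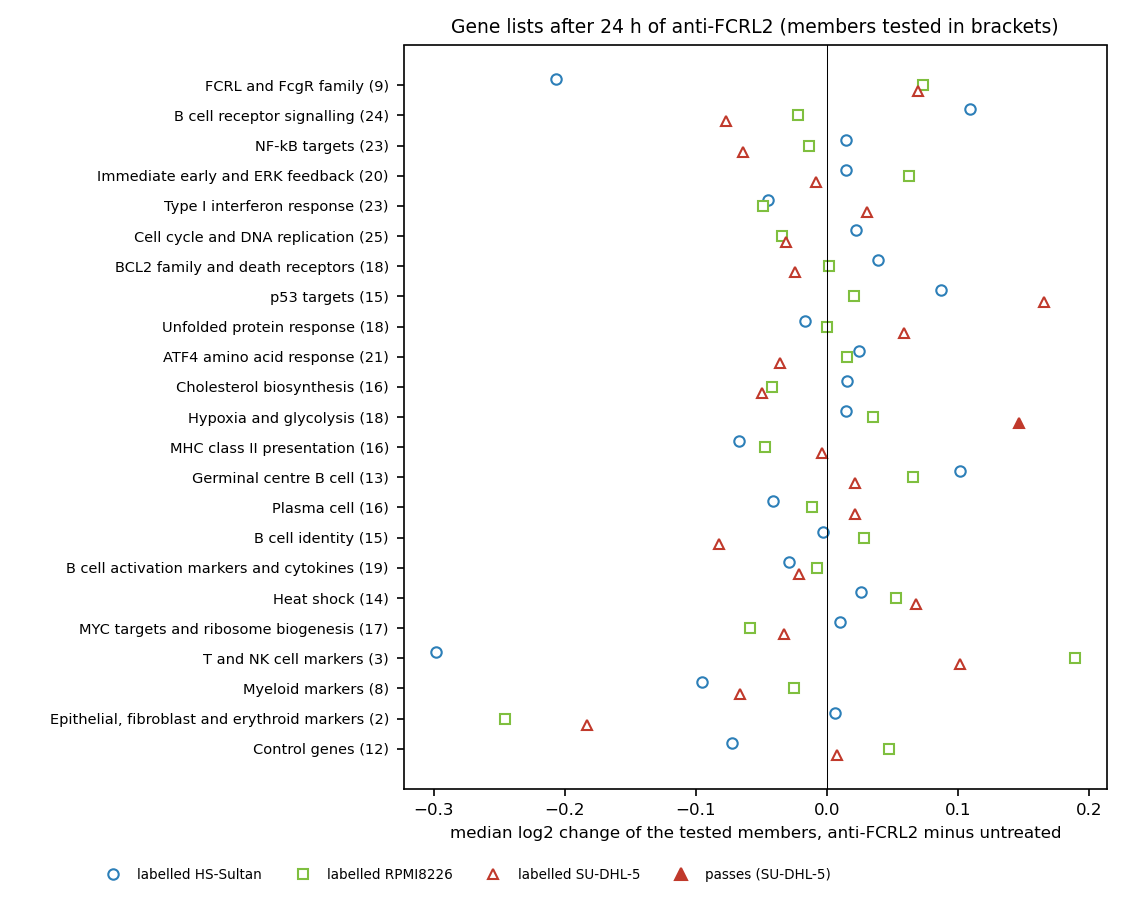
Median log2 change with the antibodies (x axis) of the members of 23 gene lists (y axis) in each line. The 1 list that passed, hypoxia and glycolysis in SU-DHL-5, has a median of 0.15, and lists that did not pass lie as far from 0 or farther, such as p53 targets in SU-DHL-5 (0.17) and the FCRL and Fc gamma receptor family in HS-Sultan (−0.21).

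Between the lines without antibodies, the arrays labelled HS-Sultan and RPMI8226 both held the germinal centre genes BCL6, BACH2, RGS13 and MME well above background and differed in the amounts of several genes. MME, the surface peptidase CD10, was lower in HS-Sultan (9.69 ± 0.030 against 10.74 ± 0.051, SD, n = 2; 2.07-fold, limma adjusted p = 0.00035), as were SERPINA9, a serpin of germinal centre B cells (6.02 ± 0.018 against 7.70 ± 0.13, 3.20-fold, adjusted p = 5.0e-05; a log2 difference of −1.68, and −0.91 without background correction), and CD24 (8.64 ± 0.031 against 9.89 ± 0.053, 2.38-fold, adjusted p = 0.00091). Higher in HS-Sultan were LMO2, a transcriptional cofactor (9.97 ± 0.18 against 8.85 ± 0.056, 2.18-fold, adjusted p = 0.0014), FCRL5 (8.91 ± 0.16 against 7.31 ± 0.031, 3.04-fold, adjusted p = 0.00016), FCRL4 (at least 1.53-fold, adjusted p = 0.0028) and SEC11C (1.67-fold, adjusted p = 0.0042). XBP1, the transcription factor of the secretory programme, read 12.96 ± 0.099 in HS-Sultan and 11.91 ± 0.15 on the arrays labelled RPMI8226 (2.07-fold, adjusted p = 0.0012). Both arrays of the higher line lay above both of the other line in each case. The plasma cell genes IRF4, CAV1 and CREB3L2 were not above background on any untreated array of either line at the probes compared. SDC1, a defining surface marker of plasma cells, was above background on 0 of 2 untreated arrays labelled HS-Sultan and 1 of 2 labelled RPMI8226, with means of 5.11 and 5.52. Other plasma cell genes were well above background in both lines, with JCHAIN at 13.64 in HS-Sultan and 13.51 in RPMI8226 and TNFRSF17 at 9.77 and 10.05. FCRL2 was 0.41 ± 0.13 higher in HS-Sultan, which did not pass (adjusted p = 0.076, both arrays higher). It passed in 5 of 21 settings, among them the authors' values (adjusted p = 0.025) and a trended robust prior (adjusted p = 0.017), within a range of 0.017 to 0.235.

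Of the 23 lists, 8 passed between these lines with the preset correlation, and 0 with an estimated correlation. Genes of the unfolded protein response were higher in HS-Sultan (10 of 18 called, 0 lower; median 0.62, adjusted p = 2.4e-07; adjusted p = 0.064 with an estimated correlation; 12 adjusted over the list alone). So were T and NK cell markers (2 of 3 called, median 1.30, or 1.08 at the background bound; adjusted p = 0.00035; adjusted p = 0.064 with an estimated correlation), MHC class II presentation (4 of 16, 0.35, adjusted p = 0.016; adjusted p = 0.163 with an estimated correlation), the FCRL family (2 of 9, 0.36, or 0.34 at the bound; adjusted p = 0.016; adjusted p = 0.163 with an estimated correlation) and NF-kB targets (4 higher and 1 lower of 23, 0.097, or 0.089 at the bound; adjusted p = 0.018; adjusted p = 0.189 with an estimated correlation). MYC targets (0 of 17 called, median 0.21, adjusted p = 0.038) and heat shock genes (2 of 14, 0.16, adjusted p = 0.044) passed as well, with adjusted p = 0.306 and 0.189 with an estimated correlation. Control genes, which did not pass, had a median of 0.12 at the bound, so shifts near this size are not particular to these lists. Germinal centre genes were lower in HS-Sultan (5 lower and 1 higher of 13, median −0.44, adjusted p = 0.009; adjusted p = 0.191 with an estimated correlation; 6 adjusted over the list alone). The T and NK list includes PRF1, a cytotoxic granule protein that was not above background on the untreated arrays labelled RPMI8226. Myeloid markers had 2 of 8 members called higher (median 0.19, adjusted p = 0.139). Plasma cell (2 higher and 2 lower of 16, adjusted p = 0.714) and B cell identity genes (2 lower of 15, adjusted p = 0.266) did not pass as lists. In all, limma called 1421 of 17792 probes in 1098 genes, 673 higher and 748 lower in HS-Sultan, and 363 higher and 689 lower with median scaling. The count fell to 784 without untreated replicate 1 and 578 without untreated replicate 2 of HS-Sultan, and to 544 without untreated replicate 1 and 649 without untreated replicate 2 of RPMI8226.

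The arrays labelled SU-DHL-5 stood far from those labelled HS-Sultan, with germinal centre genes lower and several plasma cell genes higher. The line names below are those of the labels. BCL6, the master repressor of germinal centre B cells, read 12.81 ± 0.11 in HS-Sultan and was not above background in SU-DHL-5 (4.91 ± 0.11; at least 154-fold, adjusted p = 2.6e-11). BACH2, a repressor of plasma cell differentiation (at least 60-fold, adjusted p = 2.4e-11), RGS13, a regulator of G protein signalling (at least 26.8-fold, adjusted p = 3.1e-10), and MME (at least 17.7-fold, adjusted p = 1.0e-10) were likewise not above background in SU-DHL-5. In the other direction, IRF4 (not above background in HS-Sultan, 9.58 ± 0.034 in SU-DHL-5; at least 15.3-fold, adjusted p = 4.0e-09), the caveolin gene CAV1 (at least 29.8-fold, adjusted p = 2.1e-10), CREB3L2, a transcription factor of secretory cells (at least 31.5-fold, adjusted p = 7.1e-10), and SDC1 (at least 16.9-fold, adjusted p = 4.9e-08) were higher in SU-DHL-5. PRDM1, which encodes the plasma cell repressor Blimp-1, read 5.71 ± 0.65 in HS-Sultan, where 1 of 2 arrays was above background, and 9.77 ± 0.12 in SU-DHL-5 (adjusted p = 2.5e-07), though the other tested probe of this gene was not called. JCHAIN, the joining chain of secreted immunoglobulin, went the other way and was 8.12-fold lower in SU-DHL-5 (13.64 ± 0.17 against 10.62 ± 0.22, adjusted p = 3.3e-08). Both arrays of the higher line lay above both of the other for each of these genes. The bounds hold only for the background correction used. Without it, with background left in both lines, the log2 signals of HS-Sultan and SU-DHL-5 lay 6.14 apart for BCL6, −2.82 for IRF4, −3.81 for CAV1 and −3.79 for CREB3L2, less than the bounds, and each still passed.

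As a list, germinal centre genes were higher in HS-Sultan than in SU-DHL-5 (12 of 13 called higher, 0 lower; median 1.71, adjusted p = 3.6e-06; adjusted p = 0.078 with an estimated correlation; 12 adjusted over the list alone). The remaining member, GCSAM, read 9.72 and 9.73. Plasma cell genes were lower (9 lower and 2 higher of 16, median −0.99, or −0.77 with members at their background bound; adjusted p = 0.0016; adjusted p = 0.106 with an estimated correlation; 13 adjusted over the list alone). B cell identity genes were higher (10 higher and 2 lower of 15, median 0.70, adjusted p = 0.0083; adjusted p = 0.078 with an estimated correlation; 13 adjusted over the list alone). VPREB3 (14.39 ± 0.042 against 6.49 ± 0.70, 238-fold), BANK1 (19.3-fold) and the inhibitory coreceptor CD72 (11.3-fold) were higher in HS-Sultan, while MS4A1, which encodes CD20 (3.12-fold), and the B lineage factor EBF1 (1.95-fold) were higher in SU-DHL-5. The log2 differences of VPREB3, BANK1 and CD72 were 7.90, 4.27 and 3.49 in the main fit and as small as 6.81, 3.41 and 2.80 over the alternatives. Type I interferon response genes were lower in HS-Sultan (22 of 23 called lower, median −4.24, or −4.15 at the bound; adjusted p = 1.5e-17, and 0.0015 with an estimated correlation). NF-kB targets (17 lower and 3 higher of 23, median −1.23, adjusted p = 4.2e-06) and activation markers and cytokines (16 lower and 1 higher of 19, median −1.97, or −1.67 at the bound; adjusted p = 4.3e-09) were lower too, each at adjusted p = 0.039 with an estimated correlation. The BCL2 family (11 lower and 3 higher of 18, median −0.81, adjusted p = 0.02; adjusted p = 0.097 with an estimated correlation) and MHC class II genes (8 higher and 1 lower of 16, 0.31, adjusted p = 0.031; adjusted p = 0.132 with an estimated correlation) passed with the preset correlation. In the FCRL family (3 higher and 5 lower of 9, adjusted p = 0.191), FCRL3 was at least 19.4-fold, FCRL4 4.64-fold, FCRL5 3.74-fold and the inhibitory Fc receptor FCGR2B 5.09-fold higher in SU-DHL-5, and FCRL2 was 1.43-fold lower (adjusted p = 0.0056). For FCRL3, FCRL4, FCRL5 and FCGR2B the log2 differences were −4.47, −2.22, −1.90 and −2.35 in the main fit. Over the alternatives they were as small as −2.98, −1.35, −1.71 and −1.73. Limma called 8730 of 17792 probes, 4809 higher and 3921 lower in HS-Sultan, of which 3853 differed by 2-fold or more, and 5347 of the 9650 probes detected on all arrays. With median scaling 4963 were higher and 3425 lower. Median scaling moved the median of all probes from 0.076 to 0.12, small against the differences named.

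The arrays labelled RPMI8226 had germinal centre genes higher and several plasma cell genes lower than SU-DHL-5, measured against the same untreated SU-DHL-5 arrays as HS-Sultan was. BCL6 read 13.45 ± 0.10 on the former (at least 241-fold higher, adjusted p = 1.7e-11), BACH2 was at least 94.5-fold, MME at least 36.8-fold and RGS13 at least 26.9-fold higher, and none of the 4 was above background in untreated SU-DHL-5. IRF4 (5.10 ± 0.042 against 9.58 ± 0.034; at least 15.9-fold, adjusted p = 3.2e-09), CAV1 (at least 31.1-fold) and CREB3L2 (at least 32.9-fold) were not above background on the arrays labelled RPMI8226 and were higher in SU-DHL-5. SDC1 read 5.52 ± 0.37, with 1 of 2 arrays above background, against 9.73 ± 0.033 in SU-DHL-5 (adjusted p = 1.0e-07). TNFRSF17, the receptor BCMA of plasma cells, was 4-fold and XBP1 2.67-fold higher in SU-DHL-5 (adjusted p = 8.0e-06 for XBP1). PRDM1 read 5.28 ± 0.055 and 9.77 ± 0.12 (adjusted p = 9.7e-08), with the other tested probe not called. JCHAIN was 7.39-fold lower in SU-DHL-5, as were VPREB3 (198-fold), BANK1 (15-fold) and CD24 (at least 20.4-fold). The log2 differences of VPREB3, BANK1 and CD24 were 7.63, 3.91 and 4.78 in the main fit and as small as 6.54, 3.07 and 3.17 over the alternatives. MS4A1 was 2.96-fold higher in SU-DHL-5, and in the FCRL family FCRL3 was at least 20.3-fold, FCRL4 at least 7.10-fold and FCRL5 11.4-fold higher there. FCRL2 differed by 0.11 (adjusted p = 0.507). For each gene that passed, both arrays of the higher line lay above both of the other. Here too the bounds hold only for the background correction used: without it the log2 signals lay 6.78 apart for BCL6 and −2.89 for IRF4, and both still passed.

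As lists, germinal centre genes (12 of 13 called higher, median 1.95, adjusted p = 4.8e-07; adjusted p = 0.055 with an estimated correlation; 13 adjusted over the list alone) and B cell identity genes (12 higher and 2 lower of 15, 0.78, adjusted p = 0.0019; adjusted p = 0.055 with an estimated correlation) were higher on the arrays labelled RPMI8226. Plasma cell genes were lower (11 lower and 3 higher of 16, median −1.54, or −1.30 at the bound; adjusted p = 0.0012; adjusted p = 0.114 with an estimated correlation; 14 adjusted over the list alone). Interferon response genes (22 of 23 lower, median −4.30, or −3.80 at the bound; adjusted p = 4.6e-16, and 0.0019 with an estimated correlation), NF-kB targets (17 lower and 2 higher of 23, −1.67, adjusted p = 4.8e-07, and 0.038 with an estimated correlation) and activation markers (17 lower and 2 higher of 19, −2.12, or −1.53 at the bound; adjusted p = 6.9e-08, and 0.0496 with an estimated correlation) were lower. The BCL2 family was also lower (12 lower and 3 higher of 18, −0.72, adjusted p = 0.039; adjusted p = 0.114 with an estimated correlation). MHC class II genes, which passed between HS-Sultan and SU-DHL-5, did not pass here (median 0.41, adjusted p = 0.142). The unfolded protein response did not pass in either comparison, at −0.40 here (adjusted p = 0.22) and 0.37 for HS-Sultan minus SU-DHL-5 (adjusted p = 0.376). T and NK cell markers (2 higher and 1 lower of 3) and myeloid markers (1 higher and 3 lower of 8) did not pass. Limma called 9165 of 17792 probes, 5085 higher and 4080 lower on the arrays labelled RPMI8226, of which 4167 differed by 2-fold or more, and 5602 of the 9650 probes detected on all arrays. With median scaling 5656 were higher and 3359 lower, and the median of all probes moved from 0.067 to 0.16. Median, mean and test direction differed in sign for 1 list between HS-Sultan and RPMI8226 (immediate early genes), 2 between HS-Sultan and SU-DHL-5 (myeloid and control genes) and 1 between RPMI8226 and SU-DHL-5 (cell cycle), none of which passed.

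**Figure D3:**
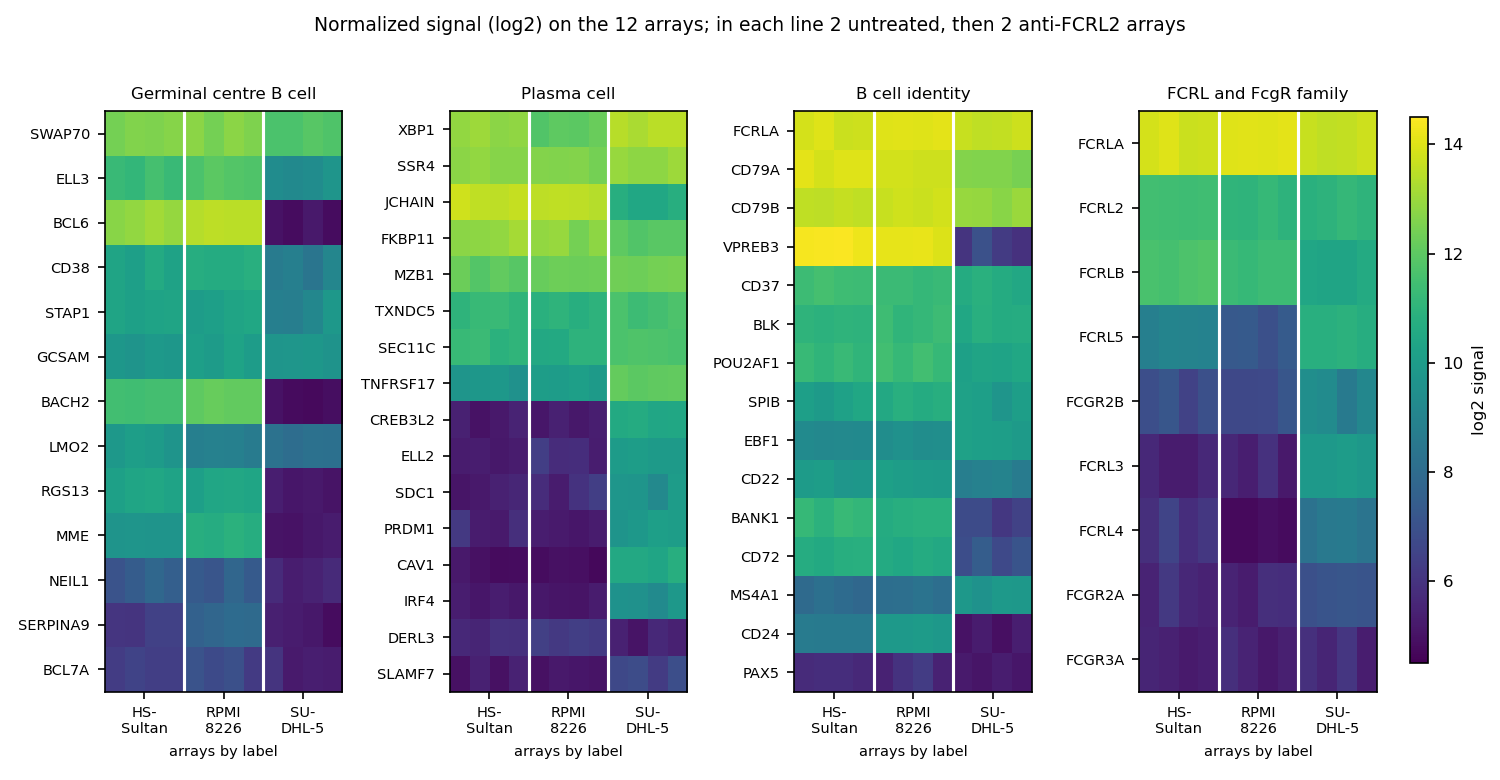
Normalized log2 signal (colour scale) of list members (y axis) on each of the 12 arrays (x axis), grouped by the line on the label, with 2 untreated then 2 treated arrays per line. BCL6, BACH2, RGS13 and MME are bright on the arrays labelled HS-Sultan and RPMI8226, and IRF4, CAV1, CREB3L2 and SDC1 on those labelled SU-DHL-5.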

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

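Leaving out the arrays labelled RPMI8226 and the naming of genes after their values were chosen only after the data were seen; the other tests here were planned. The counts of treatment calls with limma stayed at 0 in RPMI8226, SU-DHL-5, the mean over lines and the F test under the alternatives run, with unadjusted counts of 618 to 2527, 871 to 2768, 645 to 2633 and 678 to 2601. In HS-Sultan (472 to 2692 unadjusted) the count was 0 to 2 when 1 array was left out, 2 without untreated replicate 1 (CACNG8 and GCNT2), and 0 otherwise. The number of lists passing fell from 1 to 0 with median scaling, with detection p under 0.01 on all 12 arrays, with an estimated correlation, with the mean over the probes of a gene, and with the arrays labelled RPMI8226 left out. With 1 array left out it was 0 to 1, being 0 without either treated array of HS-Sultan or RPMI8226 or any of the 4 of SU-DHL-5. It stayed at 1 without background correction, with correction by moments, the authors' values, no filter, a trended robust prior, array weights and a replicate block. Between untreated HS-Sultan and RPMI8226, 849 probes were called with a replicate block and 503 at an adjusted p under 0.01, against 1421; with 1 array left out 544 to 1379. Detection on all arrays left 9650 probes to test, of which 5347 differed between HS-Sultan and SU-DHL-5 and 5602 between RPMI8226 and SU-DHL-5, fewer because fewer were tested; with 1 array left out the counts were 7175 to 8740 and 7627 to 9163. Apart from that, the cause was not tested. Over named genes and alternatives, the treatment results kept sign and side of the threshold 6530 times and changed sign without passing 49 times. Those between untreated lines kept both 3106 times, newly passed 46 times, no longer passed 79 times and changed sign without passing 25 times, such as PRDM1 between HS-Sultan and RPMI8226 (0.44, at lowest −0.02) and GCSAM between HS-Sultan and SU-DHL-5 (−0.02, at highest 0.14). No difference that had passed changed sign. Where an array was left out, its group kept 1 array, assumed to vary like the other groups. Deviations of treated and untreated replicates with the same number correlated across probes at −0.015, 0.0047 and −0.037, so the numbers show no pairing. A block by slide was not run, since the sources used here give no slide. Signal over background limits what could be seen: 15199 to 17098 probes per array were detected.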

Other observations

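The tests on normalization, on mixed plasma cells and on exchanged labels, and the genes named in the last paragraph, were chosen only after the result was seen; that on mixed plasma cells replaced a count of marker genes (1 of IRF4, PRDM1 and SDC1 above background) that had left the question open.

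The arrays labelled RPMI8226 resembled those labelled HS-Sultan, and IRF4, PRDM1, CAV1 and CREB3L2 were above background on 0 of their 2 untreated arrays although the label gives myeloma, while other plasma cell genes were high there, such as JCHAIN (13.51), MZB1 (12.25) and XBP1 (11.91). These 3 genes do not set the arrays apart. JCHAIN and MZB1 differed by 0.14 and −0.21 for untreated HS-Sultan minus RPMI8226, neither called. XBP1 was lower on the arrays labelled RPMI8226 than in HS-Sultan (1.05, HS-Sultan minus RPMI8226) and in SU-DHL-5 (−1.42, RPMI8226 minus SU-DHL-5). Normalization as the whole cause is argued against by the signals without it, where their correlation with HS-Sultan exceeded that with SU-DHL-5 by 0.094, against a spread between replicates of 0.0056. A single culture measured under both labels is argued against by the treated arrays, in which 94.9% of the 1421 probes called between the untreated arrays (1349) kept their direction. Any difference that goes with the label would do so too, so this does not separate different lines from separate cultures of 1 line. HS-Sultan cells diluted by plasma cells are argued against by 168 probes called at least 2-fold higher in untreated HS-Sultan. For 71 (42.3%, and 40.3 to 52.7% with probes chosen anew under other normalizations or none) the whole 95% interval lay above 2-fold in the treated arrays. By dilution alone, this needs plasma cells to give more than 0.5 of the RNA, while IRF4 and PRDM1 were above background on 0 of the 4 arrays labelled RPMI8226. On the untreated arrays MME, SERPINA9 and CD24 were also higher, and XBP1 and SEC11C lower, than in HS-Sultan; SDC1 was above background on 3 of the 4 arrays (5.84 ± 0.46, against 9.67 in SU-DHL-5), and a small added share of plasma cells is not excluded. Exchanged labels of RPMI8226 and SU-DHL-5 stay open. The B cell identity list had a median level of 10.05 on the arrays labelled SU-DHL-5, so as a list these genes were not lacking there. That median lay 0.82 below the mean of the medians of the other lines, within the bound of 2 written for it. The differences of single members had quartiles of 0.42 and 2.46. The demand that the upper quartile also lie under 2 was added when testing. IRF4, PRDM1 and SDC1 stood at 9.57, 9.94 and 9.67 on the arrays labelled SU-DHL-5, as an exchange would have it. Most called members of the B cell identity list were lower there. MS4A1 and EBF1 were higher there than in both other lines, against a lack of these genes. Their log2 differences were −1.64 and −0.97 for untreated HS-Sultan minus SU-DHL-5, and −1.57 and −0.71 for RPMI8226 minus SU-DHL-5. An exchange of the labels HS-Sultan and SU-DHL-5 was not tested. A difference between the lines themselves was not tested either, with 1 line per disease.

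The hypoxia and glycolysis list in SU-DHL-5 had a median change of 0.15. A single array as the carrier of the whole shift is argued against by the lowest median with 1 array left out, 0.094, although the call ended each time (adjusted p = 0.125, 0.219, 0.293 and 0.067, within 0.011 to 0.411 over 24 alternatives). Background correction as its cause is argued against by a median of 0.14 without it. With adjusted p = 0.411 with an estimated correlation, an effect of the antibodies remains a hypothesis, and culture conditions that differed between the dishes were not tested.

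For the mean effect over the 3 lines, no probe passed with limma, but 1216 had an unadjusted p under 0.05. Splitting the 4 arrays of each line into pairs anew gave as many in 3 of 100 splits, the real one included. The highest of the others was 1285, and their median was 910. A split could also keep the treated and untreated pairs of a line with the direction reversed. The split with 1285 kept these pairs in all 3 lines, in the real direction in only 1 line. It is therefore not a grouping unrelated to treatment, and the splits are not a clean measure of chance. The share of 3 in 100 is below the bound of 5 in 100 written before the test. The draw left out some of the 108 distinct splits, and their counts could raise the share above that bound, so chance is not excluded. The count says nothing about which probes changed.

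Among genes chosen after their values were seen, interferon-induced genes stood far higher on the untreated arrays labelled SU-DHL-5 than on those labelled HS-Sultan. The antiviral GTPase gene MX1 was at least 846-fold (limma, adjusted p = 2.9e-11), IFI44L at least 234-fold and IFIT3 at least 171-fold higher. IFITM1, a membrane protein that hinders virus entry, was 50.7-fold and OAS2, an RNA sensor, 14.6-fold higher. Among NF-kB targets, the chemokine gene CCL3 was 241-fold, CD83 33.5-fold and TNFAIP3, an inhibitor of the pathway, 22.5-fold higher, while the cytokine gene LTB was 11.3-fold (adjusted p = 6.3e-09) and TNF 1.92-fold lower in SU-DHL-5. Among activation markers, FCER2, which encodes CD23, was at least 159-fold and the chemokine receptor gene CCR7 112-fold higher, and CXCR5 12.4-fold lower. In each case both arrays of 1 line lay above both of the other. Against RPMI8226, where MX1 was above background on 1 of 2 arrays (5.33 against 15.37), CCL3 was 291-fold and IFITM1 31.3-fold higher in SU-DHL-5, and TNF was higher there as well (9.47 ± 0.39 against 7.09 ± 0.059, adjusted p = 5.6e-07).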
